A study of Mus musculus with 12 samples.

How the data were processed

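Bulk RNA sequencing was done on 12 libraries of NK1.1 and CD49b positive bone marrow NK cells, 3 in each of 4 groups: floxed controls without Cre (Ctrl), and Ncr1Cre mice with floxed Id2 (Id2KO), floxed Tcf7 (Tcf1KO) or both (DKO). The deposited values are FPKM, fragments scaled to gene length and library size, for 37991 genes, and these were used as the authors made them. The submitters' processing notes name Trimmomatic 0.33, TopHat2 2.1.0, HTSeq 0.6.1 and edgeR without a version, and the mouse genome mm10. The main fit used FPKM, and only the voom alternative used reads, which were recovered from them. For 23700 of the 23707 genes above 0 in any library, the values are whole multiples of what 1 read is worth. Whole reads per gene were recovered from these steps within a tolerance of 0.0010 reads, widened to at most 0.050. The voom alternative tested 12381 genes. The recovered reads summed to 99.7% to 99.8% of the library size that the values imply, and these sizes lay between 13977524 and 20209587 reads. Symbols, biotypes and positions came from GENCODE M21 on GRCm38 (mm10) for 32919 of the gene IDs, and the other 5072 kept their IDs.

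Genes with an FPKM of 1 or more in at least 3 libraries were tested, 12384 in all, on the log2 scale after adding a pseudocount of 1. A linear model with group as its term was fitted to the 12 libraries together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a variance trend). Its moderated test was two-sided, with Benjamini-Hochberg adjustment over the tested genes of each contrast and a threshold of 0.05. The contrasts were Id2KO, Tcf1KO and DKO against Ctrl, DKO against Id2KO, DKO against Tcf1KO, and the interaction, (DKO minus Tcf1KO) minus (Id2KO minus Ctrl). With groups of 3 an exact permutation test for single genes cannot reach 0.05, so limma's pooled spread was used. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

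The comparisons, tests, thresholds, gene lists, rule for named genes and settings to be varied were fixed before the data were examined. All 33 lists, drawn from textbook knowledge of NK cells and of other cells the sort could hold, had 5 or more tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and fry beside it. fry tests whether the genes of a list move, on balance, one way, and compares them with no other genes. Genes of each list were also counted by adjusted p over all genes and adjusted over the list alone. Some lists share members, such as Cd3e, which stands in the T cell receptor, ILC1, E protein target and NKT lists, and NK cells themselves express several genes of the T cell lists.

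Named genes were Id2, Tcf7 and the other Id and E protein genes; the 8 called genes with the largest change in each direction whose libraries did not overlap between groups (5 in each direction for DKO against Ctrl and against Tcf1KO); and up to 4 members of each list with the smallest p in a contrast. Predicted genes with Gm or Rik names and receptor segments were passed over, and any other gene named was chosen after its values were seen.

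The settings varied were pseudocounts of 0.1 and 0.5, no filter, a filter at FPKM 5, median scaling, quantile normalization, no variance trend, a robust variance, array weights, the replicate number as a block, a fit of only the compared groups, a threshold of 0.01, an added minimum log2 fold change of 1, and leaving out each library in turn. Alternatives chosen after seeing the data were voom on the recovered reads with and without median scaling, the Xist level as a term, an other-lineage score as a term, and leaving out the 3 libraries with the lowest array weights. The score is the mean of the scaled levels of the basophil, myeloid and erythroid marker lists. For the score Csf1, Ccl3, Il4 and Ifitm1 were left out of the basophil list. Exact permutation tests of effect covariances were likewise added afterwards. Overlaps against shared controls and the interaction of selected genes were set beside 100 simulations each.

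The procedure was tested on simulated data with the tested genes and library numbers of the study, 200 changed genes and 20 runs. It recovered 29% of genes changed by 1 on the log2 scale, 80.3% at 2 and 93.3% at 3, with 7 false calls per run on average. A raised list was called in 20 of 20 runs and 4 of 600 unchanged lists were called. These simulations drew each gene independently. Members of the real lists can move together, with an estimated correlation of 0.84 for erythroid markers, so this share of false list calls does not carry over to them. No exon or allele could be examined, since gene totals alone were analysed.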

Results

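RNA was measured in natural killer (NK) cells, lymphocytes of the innate immune system that kill infected or transformed cells. The cells were sorted from the bone marrow of C57Bl/6 mice as positive for NK1.1 and CD49b, surface molecules used to recognise NK cells in this strain. The labels write CD49b as the sorting marker and CD9b in the protocol, which was read as CD49b. Recombination was driven by Ncr1Cre, a Cre recombinase active in cells that express Ncr1 (the activating receptor NKp46). By the labels it targeted floxed Id2 (group Id2KO), floxed Tcf7, the gene of TCF-1 (group Tcf1KO), or both (group DKO). The controls (group Ctrl) carried floxed alleles without Cre, so comparisons with Ctrl also hold the presence of Cre. Each of the 4 groups had 3 libraries, 12 in all. The library sizes behind the values, computed from the steps between them, lay between 13977524 reads (Ctrl replicate 2) and 20209587 (Tcf1KO replicate 3). The labels call the samples independent but do not say whether each came from a separate animal, so the p-values measure the spread between these samples. Values are FPKM, given as mean ± SD over n = 3 libraries, and log2 fold changes are on the log2(FPKM + 1) scale with their standard error (SE), which understates changes of low genes.

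The targeted genes came first. Id2 (ENSMUSG00000020644, chromosome 12, 25093799 to 25097140, minus strand, GRCm38) encodes a helix-loop-helix protein that binds E proteins and keeps them from DNA. Its RNA stood at 152 ± 25 FPKM in Ctrl, 18 ± 1.04 in Id2KO, 114 ± 11.6 in Tcf1KO and 42.3 ± 6.08 in DKO (SD, n = 3). Each Id2KO library (17.8, 17.1 and 19.2 FPKM) and each DKO library (48.8, 41.2 and 36.8) lay below every library of the groups in which Id2 was not targeted, whose values were 124, 163 and 170.0 in Ctrl and 114, 102 and 126 in Tcf1KO. Id2 RNA fell in Id2KO (log2 fold change -3.0 ± 0.16 (SE), adjusted p = 1.52e-05) and in DKO (log2 fold change -1.82 ± 0.16 (SE), adjusted p = 0.00269). DKO kept more of it than Id2KO (log2 fold change 1.18 ± 0.16 (SE), adjusted p = 0.0205).

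Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014, minus strand) encodes TCF-1, a transcription factor of early lymphoid and T cell development. Its RNA was not lower in the libraries labelled Tcf1KO by more than the spread: 40.9 ± 4.81 FPKM in Ctrl, 84.8 ± 6.33 in Id2KO, 35 ± 4.65 in Tcf1KO and 62.4 ± 9.94 in DKO (SD, n = 3). The single values were 37.7, 38.6 and 46.5 in Ctrl, 81.5, 92.1 and 80.9 in Id2KO, 29.6, 37.3 and 38 in Tcf1KO, and 53.9, 60 and 73.3 in DKO. The difference between Tcf1KO and Ctrl was -0.22 ± 0.16 (adjusted p = 0.999), and that between DKO and Id2KO was -0.45 ± 0.16 (adjusted p = 0.328). A value for the whole gene covers exons outside a floxed segment as well, so it does not check the labels of these groups, and directions given below for Tcf1KO and DKO rest on the labels.

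**Figure D1:**
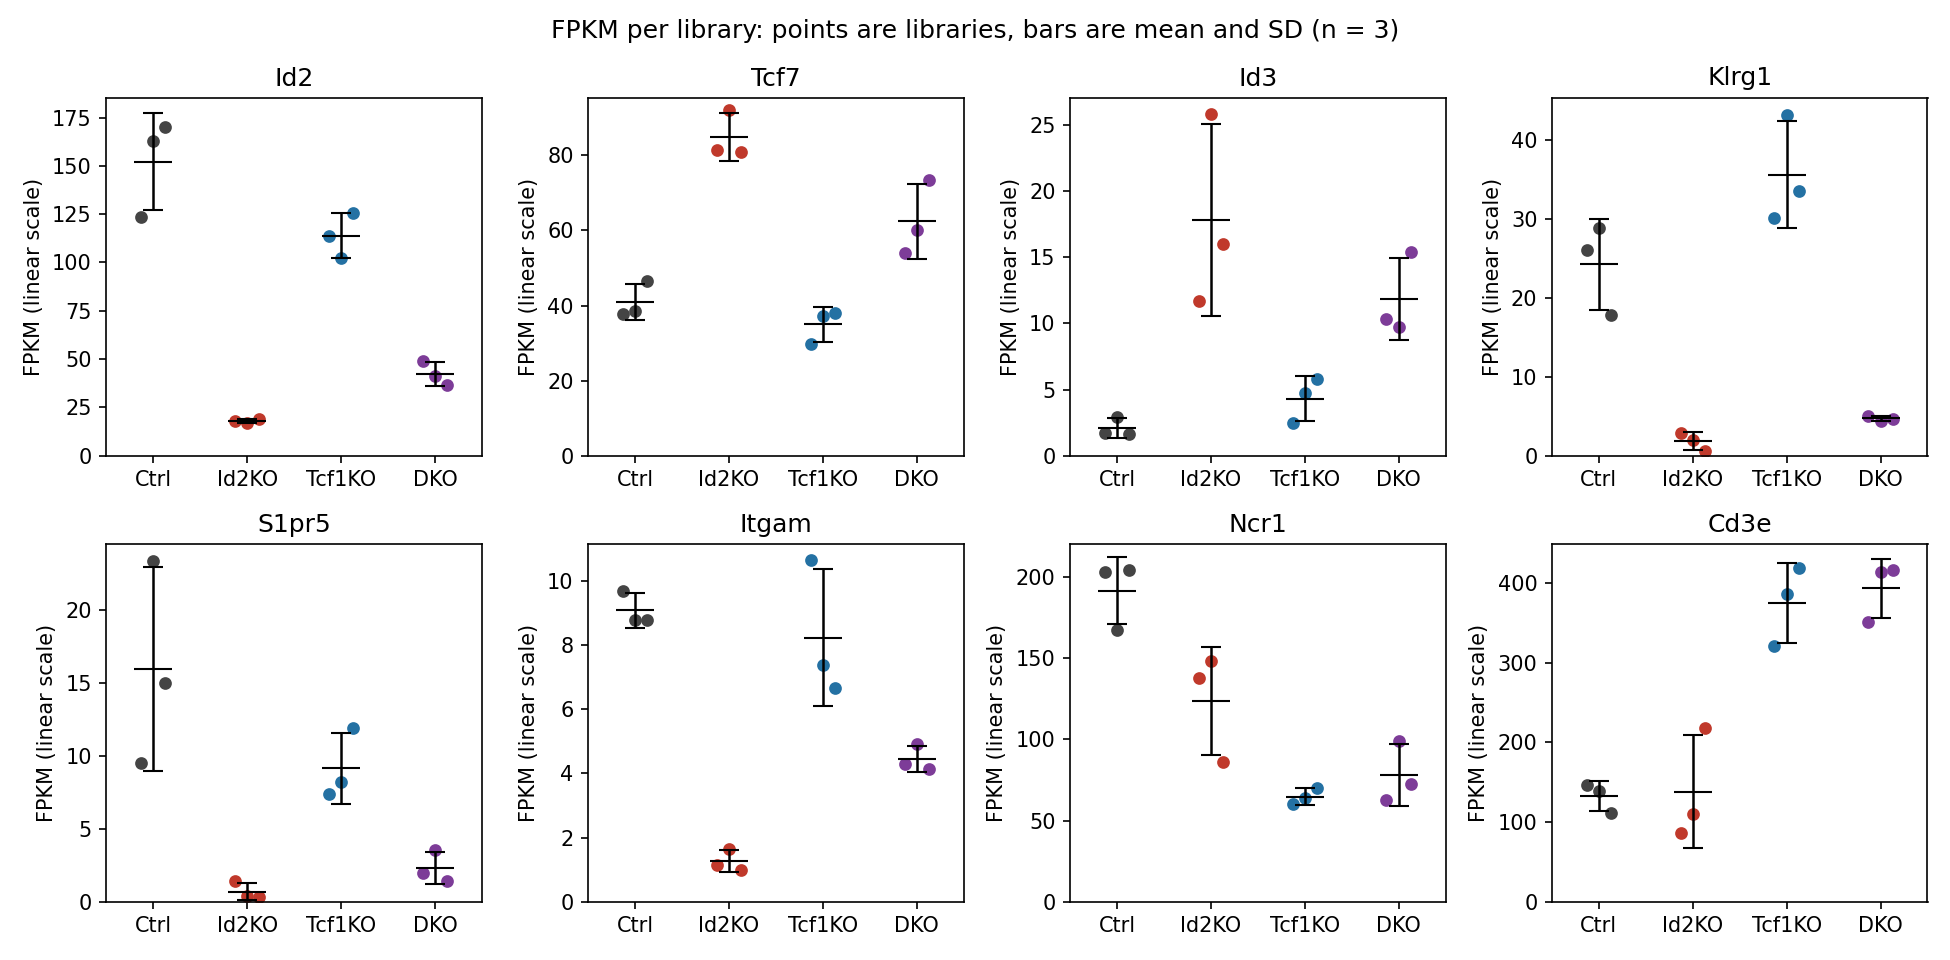
FPKM of 8 genes on a linear vertical axis for the 4 groups on the horizontal axis; points are libraries, and bars are the mean and SD of n = 3. Id2 was lowest in Id2KO (18 ± 1.04 FPKM) and Tcf7 stood at 35 ± 4.65 FPKM in Tcf1KO against 40.9 ± 4.81 in Ctrl, while Klrg1 and S1pr5 were low in Id2KO and DKO and Cd3e was higher in Tcf1KO and DKO.

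The comparison of Id2KO with Ctrl addressed the effect of targeting Id2 alone. Genes that mark terminally mature NK cells had less RNA in Id2KO. Klrg1, an inhibitory lectin-like receptor of mature NK cells (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882, minus strand), fell from 24.3 ± 5.78 to 1.86 ± 1.13 FPKM (SD, n = 3; log2 fold change -3.2 ± 0.29 (SE), adjusted p = 0.00109). S1pr5, a sphingosine-1-phosphate receptor that lets NK cells leave the bone marrow (ENSMUSG00000045087, chromosome 9, 21242912 to 21248443, minus strand), fell from 16 ± 6.99 to 0.708 ± 0.606 FPKM (log2 fold change -3.28 ± 0.36 (SE), adjusted p = 0.00298). Itgam, the CD11b integrin chain, fell from 9.08 ± 0.534 to 1.26 ± 0.339 FPKM (adjusted p = 0.000974). In the other direction, Id3, an Id family gene that E proteins can induce (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755, plus strand), rose from 2.1 ± 0.726 to 17.8 ± 7.24 FPKM (log2 fold change 2.56 ± 0.33 (SE), adjusted p = 0.0102). Tcf7 itself rose by 1.04 ± 0.16 (adjusted p = 0.0279).

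Of 12384 genes tested with limma, 22 passed an adjusted p of 0.05 in Id2KO against Ctrl, 13 higher and 9 lower. The libraries of the 2 groups did not overlap in 1716 of all tested genes (13.9%, against 10% by chance at 3 against 3). The other genes that fell included Klrb1b, an inhibitory NKR-P1 receptor (33.5 ± 6.62 to 4.63 ± 1.88 FPKM, adjusted p = 0.00185), and Fgl2, a secreted or membrane-bound fibrinogen-like protein (38.9 ± 3.34 to 8.75 ± 1.92, adjusted p = 0.00454). Klra9, a Ly49 receptor, fell as well (-1.9 ± 0.27, adjusted p = 0.0193), as did Slc27a4, a fatty acid transport protein (-1.56 ± 0.24, adjusted p = 0.0282). The genes that rose included Nsg2, a gene of thymocytes and naive T cells (6.16 ± 0.834 to 33.4 ± 4.76 FPKM, adjusted p = 0.000974), and Cd163l1, a scavenger receptor of gamma delta T cells (0.343 ± 0.302 to 6.03 ± 1.09, adjusted p = 0.00217). Drc1, a gene of cilia, rose as well (0.647 ± 0.566 to 11.3 ± 6.24, adjusted p = 0.0274). Sult5a1, a sulfotransferase family gene, rose from 0.0173 ± 0.0299 to 4.69 ± 1.56 FPKM (adjusted p = 0.00141). Plcd3, a phospholipase C, rose from 0.388 ± 0.189 to 3.45 ± 1.2 FPKM (adjusted p = 0.0279). Clip3 and Mcoln2 rose by 1.69 ± 0.27 and 1.44 ± 0.24 (adjusted p = 0.0433 for both).

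Mature NK markers fell as a group: 24 of 28 members had a negative fold change, with a median of -0.47 (camera, adjusted p = 4.14e-15; adjusted p = 0.00539 with an estimated correlation). Over all genes 3 members fell and 0 rose, and 13 fell when adjusted over the list alone. Beyond Klrg1, S1pr5 and Itgam these included Gzmb, a granzyme of cytotoxic granules (118 ± 26.5 to 26.8 ± 7.64 FPKM), Prdm1, which encodes the maturation factor Blimp-1 (8.4 ± 2.76 to 2.08 ± 0.954), and Prf1, the gene of perforin (71.3 ± 6.9 to 24.1 ± 1.57). Their adjusted p over all genes was 0.0506, 0.0506 and 0.0603. Cytotoxic effectors had 18 of 22 members with a negative fold change (adjusted p = 6.09e-05; adjusted p = 0.182 with an estimated correlation); 0 members fell over all genes and 3 adjusted over the list alone, namely Gzmb, Prf1 and Gzma. The list of Ly49 receptors, which sense MHC class I, and NKR-P1 receptors had 12 of 16 members lower (adjusted p = 6.29e-05, and adjusted p = 0.362 with an estimated correlation). Of these 2 fell over all genes and 3 adjusted over the list alone. Reads of these near-identical receptor genes can be divided differently between copies, so single Ly49 values are uncertain. Trafficking receptors and integrins had 18 of 29 members lower (adjusted p = 0.0146; adjusted p = 0.182 with an estimated correlation), with 2 falling over all genes. Adjusted over the list alone 5 fell and 2 rose, the latter being Cxcr5 (1.76 ± 0.31, adjusted p = 0.0624 over all genes) and Cxcr3 (0.97 ± 0.18, adjusted p = 0.0832). NK transcription factors (23 of 39 members, adjusted p = 0.0155) and NK activating and inhibitory receptors (19 of 30, adjusted p = 0.0344) were lower with the preset correlation. With an estimated correlation they had adjusted p = 0.487 and adjusted p = 0.465. Of the former 3 fell and 2 rose adjusted over the list alone, and of the latter 3 fell and 0 rose. Among the lists of this paragraph only mature NK markers passed with an estimated correlation.

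Some lists of genes of less mature NK cells and of T cells were higher with the preset correlation. Immature NK markers were higher in 12 of 20 members (adjusted p = 0.0149; adjusted p = 0.182 with an estimated correlation), with 1 rising over all genes, 7 rising adjusted over the list alone, and 1 falling. They included Cd27, a costimulatory receptor lost during NK maturation (57.2 ± 2.86 to 99.6 ± 14.6 FPKM, adjusted p = 0.108 over all genes), and Emb (0.76 ± 0.13, adjusted p = 0.0624). The naive T and T memory program had 24 of 32 members higher (adjusted p = 1.39e-05; adjusted p = 0.195 with an estimated correlation), 3 over all genes and 8 adjusted over the list alone. T cell receptor complex genes were higher in 11 of 17 members (adjusted p = 0.00185; adjusted p = 0.362 with an estimated correlation). Cd3d, a CD3 chain, rose from 28.1 ± 1.61 to 77.4 ± 22.7 FPKM (adjusted p = 0.0183); 4 members rose adjusted over the list alone. The mean level of the list was 0.0052, 0.29 and 0.52 in Id2KO replicates 1, 2 and 3, against up to 0.12 in Ctrl. E protein target genes were higher in 11 of 21 members (adjusted p = 0.0302; adjusted p = 0.465 with an estimated correlation), with 2 rising over all genes and 4 adjusted over the list alone. Without the 3 libraries that stand apart, among them Id2KO replicate 3, the immature NK, T cell receptor and E protein target lists lost their calls (adjusted p = 0.206, 0.127 and 0.675). The naive T list kept its call (adjusted p = 0.00885). The E proteins Tcf3, Tcf4 and Tcf12 differed by -0.31, -0.28 and 0.34 (adjusted p = 0.591, 0.727 and 0.426), and Id1 by -0.61 (adjusted p = 0.671). Oxidative phosphorylation genes had 28 of 34 members higher with a median of 0.18 (adjusted p = 0.00296; adjusted p = 0.465 with an estimated correlation) and 0 called over all genes or adjusted over the list alone.

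Markers of other bone marrow cells were lower in Id2KO than in Ctrl beside these groups. Myeloid and neutrophil markers had a median of -3.04 over 19 genes (adjusted p = 2.44e-10; adjusted p = 0.203 with an estimated correlation). The median was -1.97 for erythroid markers, over 13 (adjusted p = 6.09e-05; adjusted p = 0.465 with an estimated correlation). For basophil and mast cell markers it was -1.86 over 12 (adjusted p = 1.79e-06; adjusted p = 0.402 with an estimated correlation). Adjusted over the list alone, 11, 0 and 3 of their members fell, and 0 of each list fell over all genes. S100a8, a neutrophil gene named after its values were seen, stood at 4.48, 69.4 and 331 FPKM in the Id2KO libraries and at 667, 1680.4 and 295 in Ctrl. With a score of these 3 marker lists as a term in the fit, a setting chosen after seeing the data, 11 genes passed, and without the 3 libraries that stand apart 8 did. The count was 13 without Id2KO replicate 1, 14 without Id2KO replicate 2 and 2 in a fit of these 2 groups alone, whose spread rests on 6 libraries. Id2, Klrg1, S1pr5, Itgam, Klrb1b, Fgl2, Nsg2, Cd163l1 and Sult5a1 passed in each of the 12 fits that leave out 1 library, Id3 in 11 (adjusted p = 0.0506 without Ctrl replicate 1), and Tcf7 in 4 (highest adjusted p = 0.13, without Id2KO replicate 2). Klra9 passed in 9, Drc1 and Cd3d in 8, Slc27a4 in 4, Plcd3 in 3, Clip3 in 2 and Mcoln2 in 1 of these fits.

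**Figure D2:**
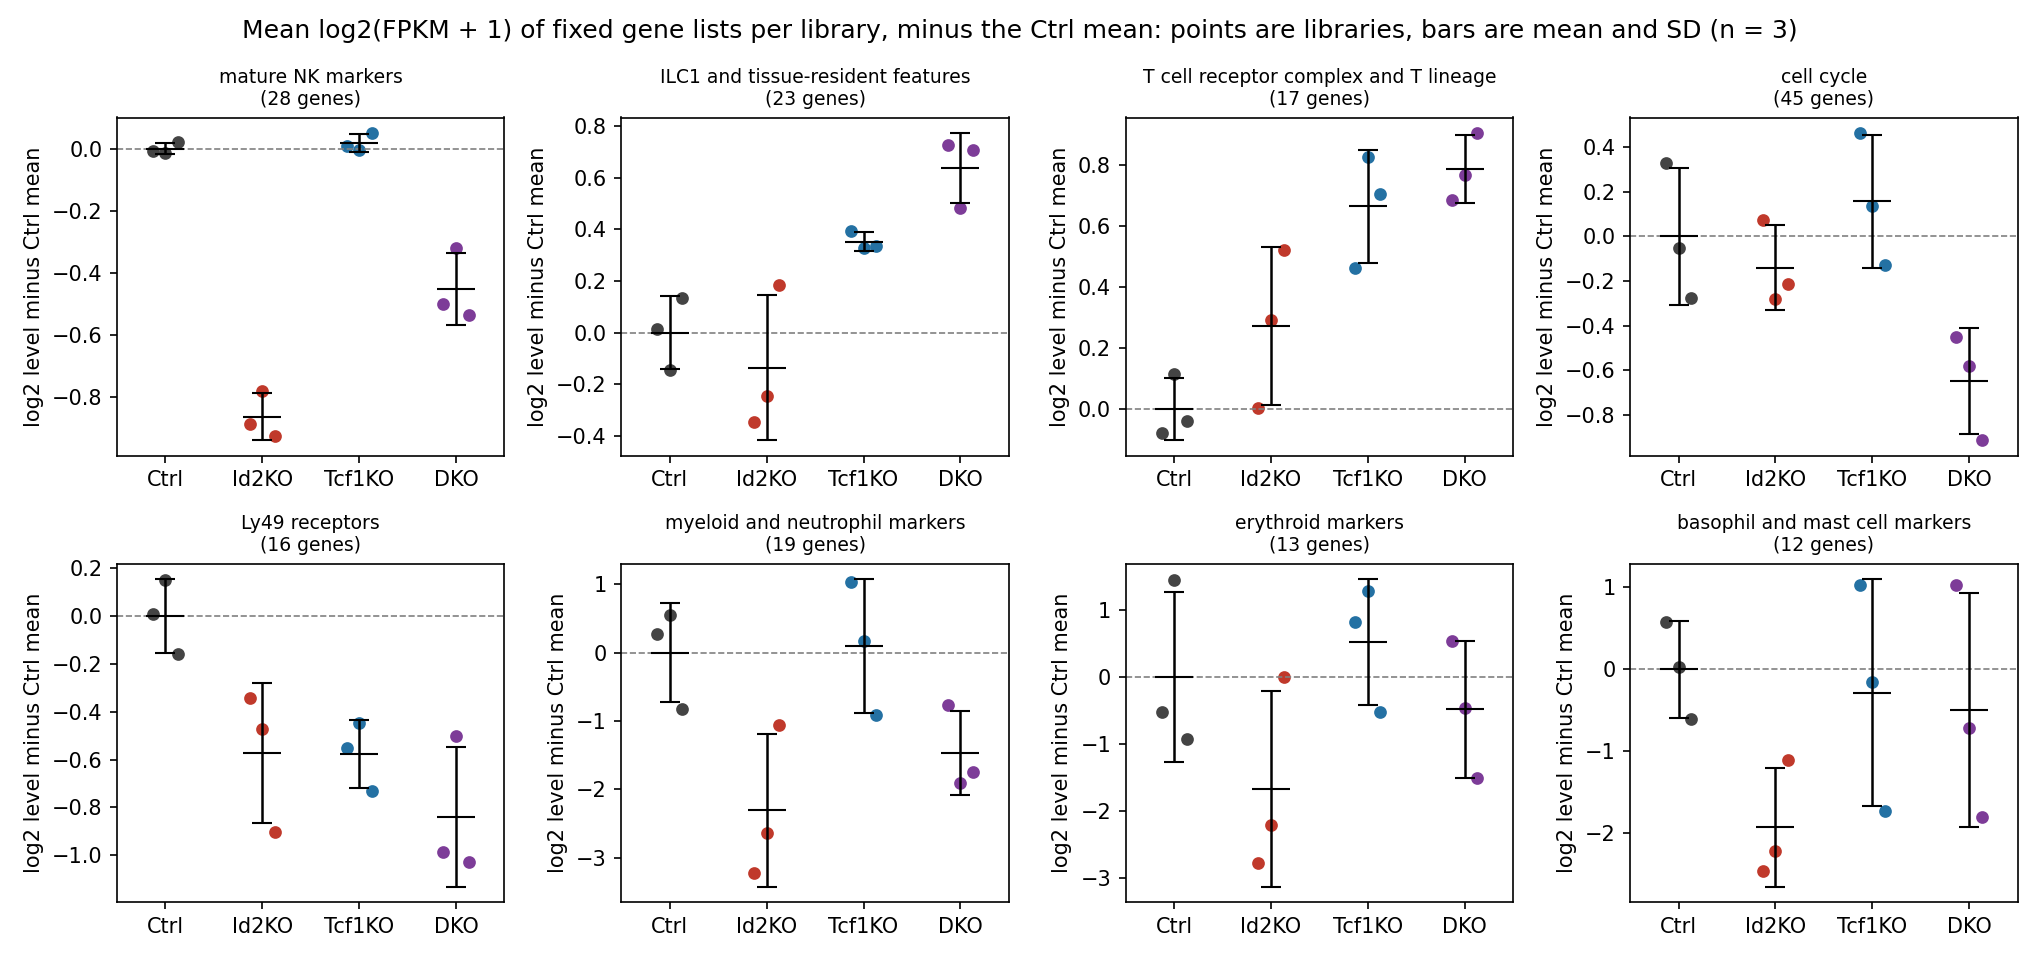
Mean log2(FPKM + 1) over the tested genes of 8 fixed lists, minus the mean of the Ctrl libraries (vertical axis), in the 4 groups (horizontal axis); points are libraries, and bars are the mean and SD of n = 3. Mature NK markers lay at -0.89, -0.78 and -0.93 in Id2KO, and the myeloid, erythroid and basophil lists varied widely between libraries of 1 group.

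The comparison of Tcf1KO with Ctrl addressed the effect of targeting Tcf7 alone. No gene passed the threshold, and genes such as Klra4 and Cd3e were among those that differed beyond the range of the libraries. Klra4, the activating receptor Ly49D, stood at 70.3 ± 2.61 FPKM in Ctrl and 20.9 ± 5.47 in the libraries labelled Tcf1KO (SD, n = 3; adjusted p = 0.143). Cd3e, a CD3 chain of the T cell receptor complex, stood at 132 ± 18.7 and 375 ± 50.1 FPKM (adjusted p = 0.195). Itga1, the CD49a integrin of tissue-resident cells, stood at 2.3 ± 0.717 and 6.29 ± 0.857 FPKM (adjusted p = 0.195). Ncr1 (ENSMUSG00000062524, chromosome 7, 4337724 to 4345164, plus strand), the gene whose locus drives Cre here, stood at 192 ± 20.8 FPKM in Ctrl and lower on average in all 3 groups with Cre. It was 124 ± 33.3 in Id2KO, 64.8 ± 5.14 in Tcf1KO and 78.1 ± 18.9 in DKO (adjusted p = 0.346, 0.143 and 0.0567), so its values are not assigned to Tcf7. In these 4 genes the libraries of Tcf1KO and Ctrl did not overlap, as in 1323 of all tested genes (10.7%, against 10% by chance at 3 against 3).

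With limma 0 genes passed, while 594 of 12384 had an unadjusted p under 0.05, and voom on recovered reads called 4. T cell receptor complex genes were higher in 13 of 17 members, with a median of 0.72 (adjusted p = 7.70e-09; adjusted p = 0.11 with an estimated correlation); 0 rose over all genes and 10 adjusted over the list alone. These included Cd3d (1.14 ± 0.20), Cd3g (0.96 ± 0.22) and Trac, the T cell receptor alpha constant gene (175 ± 29.4 to 430.2 ± 82.9 FPKM), with adjusted p = 0.171, 0.328 and 0.298 over all genes. Markers of invariant NKT and gamma delta T cells, which can share the NK1.1 gate, were higher in 10 of 13 members (median 0.84, adjusted p = 1.99e-06; adjusted p = 0.0899 with an estimated correlation). Among them 4 rose adjusted over the list alone and 0 over all genes. ILC1 and tissue-resident features were higher in 16 of 23 members (adjusted p = 0.000115; adjusted p = 0.11 with an estimated correlation), 6 adjusted over the list alone and 0 over all genes, Tnfsf10, the gene of TRAIL, among them (0.98 ± 0.24). Ly49 and NKR-P1 receptors were lower in 13 of 16 members (median -0.52, adjusted p = 2.03e-07; adjusted p = 0.284 with an estimated correlation), 6 adjusted over the list alone and 0 over all genes. Cell cycle genes were higher in 34 of 45 members (adjusted p = 0.0485; adjusted p = 0.906 with an estimated correlation), 0 of them adjusted over the list alone or over all genes, and adjusted p = 0.126 without the 3 libraries that stand apart. Mature NK markers had a median of -0.15 and a mean of 0.019 (adjusted p = 0.654), and Wnt and TCF target genes a median of -0.067 (adjusted p = 0.247). Leaving out Id2KO replicate 3, which enters only through the shared spread, gave 3 calls, and array weights gave 7. The number of lists called was 5, and 9 without Ctrl replicate 2 and 10 without Tcf1KO replicate 3.

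In DKO against Ctrl, the effect of targeting both genes, Klrg1 and S1pr5 were again low and Id3 was high. Klrg1 fell to 4.73 ± 0.311 FPKM (log2 fold change -2.11 ± 0.29 (SE), adjusted p = 0.0298), S1pr5 to 2.31 ± 1.1 (adjusted p = 0.0424) and the Ly49 gene Klra4 to 19.1 ± 4.76 (adjusted p = 0.0416; SD, n = 3). Id3 rose to 11.8 ± 3.1 FPKM (adjusted p = 0.0468) and Nsg2 to 19.5 ± 3.01 (adjusted p = 0.0291). Apobec2, a deaminase family gene, rose from 0.115 ± 0.157 to 2.44 ± 0.188 FPKM (log2 fold change 1.63 ± 0.20 (SE), adjusted p = 0.0253). Vegfc, a lymphatic growth factor, fell from 6.42 ± 1.77 to 0.066 ± 0.069 FPKM (adjusted p = 0.0327).

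Here 18 genes passed in limma's test, 7 higher and 11 lower, and the libraries of the 2 groups did not overlap in 1678 of all tested genes (13.5%, against 10% by chance at 3 against 3). The called genes also held Cables1 (1.24 ± 0.20, adjusted p = 0.0468) and the Ly49 pseudogene Klra14-ps (-2.35 ± 0.27, adjusted p = 0.0229). n-R5s39, annotated as ribosomal RNA, was listed at 0 in every Ctrl library and at 8.66, 4.11 and 4.54 FPKM in DKO (adjusted p = 0.0291). Mature NK markers fell as a group, with 21 of 28 lower and a median of -0.47 (adjusted p = 3.10e-06; adjusted p = 0.0369 with an estimated correlation). Of these 2 fell over all genes, and 14 fell and 4 rose adjusted over the list alone, among the falling ones Cma1, a chymase gene (-2.34 ± 0.46, adjusted p = 0.0976 over all genes), and Itgam (-0.89 ± 0.19, adjusted p = 0.122). T cell receptor complex genes rose as a group in 16 of 17 members (median 0.93, adjusted p = 2.92e-11; adjusted p = 0.0369 with an estimated correlation), 11 adjusted over the list alone and 0 over all genes. Cd3e stood at 393 ± 37 FPKM (adjusted p = 0.0713) and Trac at 476 ± 26.4 (adjusted p = 0.0713). Invariant NKT and gamma delta T cell markers rose as a group beside them in 11 of 13 members (median 1.2, adjusted p = 2.90e-08; adjusted p = 0.0284 with an estimated correlation), 8 adjusted over the list alone and 0 over all genes. ILC1 and tissue-resident features rose as a group in 20 of 23 members (median 0.91, adjusted p = 1.88e-08; adjusted p = 0.0284 with an estimated correlation), 9 adjusted over the list alone and 0 over all genes. They included Itga1 (7.12 ± 1.63 FPKM, adjusted p = 0.0504), Inpp4b (1.04 ± 0.23) and Il21r (1.41 ± 0.28). With the other-lineage score as a term and an estimated correlation the T cell receptor complex list no longer passed (adjusted p = 0.0735). The mature NK, NKT and ILC1 lists still passed (adjusted p = 0.0239, 0.0227 and 0.0239).

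Cell cycle genes were lower in 45 of 45 members in DKO than in Ctrl (median -0.63, adjusted p = 1.14e-17; adjusted p = 0.219 with an estimated correlation). 8 fell adjusted over the list alone and 0 over all genes, the former including Cdk1, the mitotic kinase (3.22 ± 0.637 to 1.49 ± 0.254 FPKM), and Mki67 (173 ± 57.3 to 75.6 ± 26.5), with adjusted p = 0.148 and 0.162 over all genes. Ly49 and NKR-P1 receptors were lower in 14 of 16 members (adjusted p = 2.51e-09; adjusted p = 0.145 with an estimated correlation), 2 over all genes and 8 adjusted over the list alone. Interferon-stimulated genes were lower in 24 of 30 (adjusted p = 1.43e-05; adjusted p = 0.287 with an estimated correlation), 0 over all genes and 2 adjusted over the list alone, namely Irf7 and Bst2. Myeloid and neutrophil markers moved with these groups at a median of -1.61 (adjusted p = 3.40e-06; adjusted p = 0.312 with an estimated correlation), with 0 members falling adjusted over the list alone or over all genes. Naive T and T memory genes (20 of 32 higher, adjusted p = 0.000237), E protein targets (14 of 21, adjusted p = 0.000537) and immature NK markers (15 of 20, adjusted p = 0.025) were higher with the preset correlation. Their values with an estimated correlation were adjusted p = 0.242, 0.258 and 0.164. Over all genes 2, 1 and 0 of their members rose, and adjusted over the list alone 8, 6 and 4 rose. Immediate early genes, which handling of cells can induce, were higher in 29 of 30 members (adjusted p = 0.025; adjusted p = 0.728 with an estimated correlation). Their mean level ran from -0.68 to 0.95 within Ctrl. Also called with the preset correlation were higher cytokines and chemokines (12 of 17, adjusted p = 0.0461) and lower progenitor markers (8 of 8, adjusted p = 0.019). With an estimated correlation they had adjusted p = 0.425 and 0.425. The immature NK, cytokine and progenitor lists had adjusted p = 0.159, 0.157 and 0.267 without the 3 libraries that stand apart. The immediate early list then changed direction (adjusted p = 0.275). The count of called genes was 1 without Ctrl replicate 1, 1 without Ctrl replicate 2 and 3 without Ctrl replicate 3. It was 5, 11 and 1 without DKO replicates 1, 2 and 3, and 3 and 10 without Tcf1KO replicates 2 and 3, and 27 without Id2KO replicate 3. Of the genes named here only Id2 passed in each of the 12 fits that leave out 1 library. Klra14-ps and Nsg2 passed in 7, n-R5s39 in 6, Apobec2 and Vegfc in 5, Klrg1 in 4, Klra4 in 3, Id3 and S1pr5 in 2 and Cables1 in 0. Without the 3 libraries that stand apart 0 genes passed.

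Both Id2KO and DKO were compared with the same Ctrl libraries. They shared 2 genes that rose (Id3 and Nsg2) and 3 that fell (Id2, Klrg1 and S1pr5). Independent lists of these sizes would share 0.00735 and 0.00799, and unchanged groups simulated against the same controls shared 0 in 100 simulations. Such groups give almost no calls, so this does not bound the overlap. Across genes, which are not independent replicates, the fold changes had a covariance of 0.129 against 0.080 simulated, and a correlation of 0.50 against 0.50. With 3 controls the controls cannot be divided into sets of at least 2 libraries, so part of the excess may come from the shared controls. The overlap was 1 without Ctrl replicate 1, 1 without Ctrl replicate 2, 3 without Ctrl replicate 3, 1 without DKO replicate 3, and 2 without DKO replicate 1, Tcf1KO replicate 2 or Tcf1KO replicate 3.

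In DKO against Id2KO, the effect of targeting Tcf7 beside Id2, Fgl2, Klrb1b and Itgam were among the genes that rose. These were also low in Id2KO against Ctrl, and since both contrasts use the Id2KO libraries, opposite changes can come from that sharing alone. Fgl2 rose from 8.75 ± 1.92 to 59.1 ± 12.5 FPKM (SD, n = 3; log2 fold change 2.62 ± 0.24 (SE), adjusted p = 0.00361). Klrb1b rose from 4.63 ± 1.88 to 23.5 ± 3.26 (log2 fold change 2.18 ± 0.27 (SE), adjusted p = 0.0121) and Itgam from 1.26 ± 0.339 to 4.45 ± 0.418 (adjusted p = 0.0311). Itga1 (ENSMUSG00000042284, chromosome 13, 114953096 to 115101964, minus strand) rose from 1.02 ± 0.0298 to 7.12 ± 1.63 FPKM (log2 fold change 1.99 ± 0.21 (SE), adjusted p = 0.0069), and Cd226, the activating receptor DNAM-1, from 11.6 ± 1.24 to 28.8 ± 2.36 (adjusted p = 0.0205). Sult5a1 and Plcd3 fell to 0.0421 ± 0.0729 and 0.0747 ± 0.0975 FPKM (adjusted p = 0.00402 and 0.0121). Tcf7 RNA was not lower in the libraries labelled DKO than in Ctrl. It was lower in each DKO library than in each Id2KO library (log2 fold change -0.45, limma, adjusted p = 0.328). The libraries of these 2 groups did not overlap in 14.7% of tested genes. The directions of the genes above therefore rest on the labels. Id2 RNA was higher in DKO than in Id2KO (log2 fold change 1.18, limma, adjusted p = 0.0205). The contrast thus also holds a different level of Id2, and its part in these changes was not tested.

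Of the genes tested with limma 15 passed, 10 higher and 5 lower. They also included Entpd1, the ectonucleotidase CD39 (0.897 ± 0.482 to 4.33 ± 0.859 FPKM, adjusted p = 0.0311), Apobec2 (adjusted p = 0.0226) and the ribosomal RNA gene n-R5s39 (adjusted p = 0.0369) among those that rose. Plxnc1, a semaphorin receptor (17.6 ± 2.16 to 6.09 ± 1.46 FPKM, adjusted p = 0.0106), Pbk, a mitotic kinase (7.36 ± 0.386 to 3.0 ± 0.135, adjusted p = 0.0284), and Lsm4, a splicing factor gene (-0.98 ± 0.15, adjusted p = 0.0369), fell. ILC1 and tissue-resident features rose as a group in 21 of 23 members (median 0.64, adjusted p = 5.80e-10; adjusted p = 0.0301 with an estimated correlation), 1 over all genes and 7 adjusted over the list alone, including Cd3e (1.61 ± 0.28) and Tnfsf10 (1.13 ± 0.24). With the other-lineage score as a term the list no longer passed (adjusted p = 0.0916 with an estimated correlation). Mature NK markers were higher in 22 of 28 members (median 0.26, adjusted p = 3.79e-05; adjusted p = 0.0972 with an estimated correlation), 1 over all genes and 6 adjusted over the list alone. T cell receptor complex genes were higher in 11 of 17 (adjusted p = 0.00252; adjusted p = 0.415 with an estimated correlation), 0 over all genes and 5 adjusted over the list alone. Beside them NKT and gamma delta T cell markers were higher in 11 of 13 (adjusted p = 0.000894; adjusted p = 0.165 with an estimated correlation). Of the latter 5 rose and 1 fell adjusted over the list alone, and 0 passed over all genes. Cytokines and chemokines were higher in 12 of 17 (adjusted p = 0.00252; adjusted p = 0.415 with an estimated correlation). Ccl4, a chemokine, stood at 70.3 ± 15.3 in Id2KO and 202 ± 57.3 FPKM in DKO (adjusted p = 0.0786 over all genes); of the list 0 rose over all genes and 1 adjusted over the list alone. Cell cycle genes were lower in 43 of 45 (adjusted p = 5.17e-11; adjusted p = 0.415 with an estimated correlation). Oxidative phosphorylation genes were lower in 28 of 34 (adjusted p = 0.000123; adjusted p = 0.415 with an estimated correlation). In these lists 1 and 0 members fell adjusted over the list alone and 0 over all genes. Immediate early genes were higher in 28 of 30 (adjusted p = 0.00861; adjusted p = 0.733 with an estimated correlation). Also called with the preset correlation were higher cytotoxic effectors (15 of 22, adjusted p = 0.0365), lower Ly49 and NKR-P1 receptors (11 of 16, adjusted p = 0.0388) and lower interferon-stimulated genes (22 of 30, adjusted p = 0.0183). With an estimated correlation they had adjusted p = 0.554, 0.729 and 0.728. The last 2 had adjusted p = 0.102 and 0.883 without the 3 libraries that stand apart. Other lineages stood higher in DKO than in Id2KO beside these groups: basophil and mast cell markers by a median of 1.39 (adjusted p = 0.000183; adjusted p = 0.62 with an estimated correlation). Erythroid markers stood higher by 1.28 (adjusted p = 0.00715; adjusted p = 0.729 with an estimated correlation), and myeloid markers by 0.96 (adjusted p = 0.0365; adjusted p = 0.733 with an estimated correlation). The count was 8, 2 and 31 without Id2KO replicates 1, 2 and 3, 9, 5 and 8 without DKO replicates 1, 2 and 3, and 8 with the other-lineage score as a term. Fgl2 and Sult5a1 passed in each of the 12 fits that leave out 1 library, Itga1 and Plxnc1 in 11 (adjusted p = 0.0571 and 0.0703 without Id2KO replicate 2), Klrb1b in 10, Plcd3 and Id2 in 8 and Cd226 in 7. Apobec2 passed in 5, Pbk in 4, Itgam and Entpd1 in 2 and Lsm4 and n-R5s39 in 1 of them. Without the 3 libraries that stand apart 11 genes passed, of which 2 were among the 15. Lists called numbered 14, against 7 without Id2KO replicate 1, 6 without DKO replicate 1 and 8 with the score as a term.

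In DKO against Tcf1KO, the effect of targeting Id2 beside Tcf7, Klrg1 fell from 35.7 ± 6.78 to 4.73 ± 0.311 FPKM (SD, n = 3; log2 fold change -2.66 ± 0.29 (SE), adjusted p = 0.0109). Pbk fell from 10.4 ± 1.65 to 3.0 ± 0.135 FPKM (log2 fold change -1.5 ± 0.15 (SE), adjusted p = 0.0109) and Cdk1 from 4.73 ± 0.519 to 1.49 ± 0.254 (adjusted p = 0.0484), the latter in 0 of the 12 fits that leave out 1 library. Id2 fell as well (log2 fold change -1.41 ± 0.16, adjusted p = 0.0109). Snord110, a small nucleolar RNA, rose from 1.87 ± 0.718 to 16 ± 2.8 FPKM (adjusted p = 0.0172), and n-R5s39, listed at 0 in every Tcf1KO library, was higher in DKO (adjusted p = 0.0214).

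In this comparison 7 genes passed in limma, 3 higher and 4 lower. Cell cycle genes were lower in 44 of 45 members (median -0.83, adjusted p = 4.08e-28; adjusted p = 0.184 with an estimated correlation), 1 over all genes and 22 adjusted over the list alone. Ube2c, a mitotic ubiquitin-conjugating enzyme, differed by -1.71 ± 0.36 and Mki67 by -1.45 ± 0.28 (adjusted p = 0.251 and 0.204 over all genes). Mature NK markers were lower in 20 of 28 (median -0.28, adjusted p = 3.25e-06; adjusted p = 0.12 with an estimated correlation), 1 over all genes and 8 adjusted over the list alone. These included Cx3cr1, a chemokine receptor of mature NK cells (-1.9 ± 0.41), S1pr5 (-1.65 ± 0.36) and Tbx21, the gene of T-bet (-0.73 ± 0.17). Naive T and T memory genes were higher in 26 of 32 (adjusted p = 8.59e-06; adjusted p = 0.184 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone, Cxcr5 (1.3 ± 0.31) and Id3 (1.3 ± 0.33) among the latter. Interferon-stimulated genes were lower in 29 of 30 (adjusted p = 2.95e-09; adjusted p = 0.184 with an estimated correlation). Immediate early genes were higher in 30 of 30 (adjusted p = 0.000169; adjusted p = 0.596 with an estimated correlation), with 0 members of either list passing adjusted over the list alone or over all genes. Also called with the preset correlation were higher immature NK markers (15 of 20, adjusted p = 0.00181), E protein targets (14 of 21, adjusted p = 0.00181), cytokines and chemokines (12 of 17, adjusted p = 0.00588), ILC1 features (16 of 23, adjusted p = 0.00978) and IL-15 signaling genes (22 of 28, adjusted p = 0.0189). With an estimated correlation they had adjusted p = 0.121, 0.289, 0.289, 0.249 and 0.184. Ly49 and NKR-P1 receptors were lower in 14 of 16 (adjusted p = 0.016; adjusted p = 0.596 with an estimated correlation). Without the 3 libraries that stand apart the E protein target, IL-15, Ly49, immediate early and erythroid lists had adjusted p = 0.0539, 0.055, 0.195, 0.055 and 0.084. Myeloid markers were lower beside these lists by a median of -1.39 in 19 of 19 members (adjusted p = 1.84e-07; adjusted p = 0.289 with an estimated correlation), and erythroid markers by -0.97 (adjusted p = 0.0024; adjusted p = 0.596 with an estimated correlation). No gene passed without Tcf1KO replicate 1, Tcf1KO replicate 3 or DKO replicate 3 (0 each by limma, while 601, 906 and 586 had an unadjusted p under 0.05), 1 passed without Tcf1KO replicate 2 and 2 without DKO replicate 2. In the fit without the 3 libraries that stand apart 2 genes passed, 1 of them among the 7. Pbk passed in 9 of the leave-one-out fits, Id2, Klrg1 and Snord110 in 7 and n-R5s39 in 4.

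The interaction asked whether the Id2 effect differed between the groups with Tcf7 targeted and those without. It is computed as the difference DKO minus Tcf1KO less the difference Id2KO minus Ctrl. Only Ctrl lacks Cre, so a change due to Cre stays in Id2KO minus Ctrl and cancels in DKO minus Tcf1KO. Such a change would enter the interaction with the opposite sign, and this design cannot separate it from an effect of Tcf7. Id2 itself was lower by less in the Tcf1KO background: -3.0 in Id2KO against Ctrl and -1.41 in DKO against Tcf1KO, a difference of 1.58 ± 0.23 (adjusted p = 0.085). The backgrounds may therefore not be matched for the loss of Id2 RNA. Whether smaller effects on other genes follow it was not tested. The Klrb1b difference was -2.66 in Id2KO against Ctrl and -0.22 in the Tcf1KO background, a difference of 2.44 ± 0.38 (adjusted p = 0.107). Itgam differed by 1.43 ± 0.27 (adjusted p = 0.234), Nsg2 by -1.61 ± 0.28 (adjusted p = 0.164) and Cd3d by -1.6 ± 0.28 (adjusted p = 0.164), none of them past the threshold. With limma 0 genes passed, 735 had an unadjusted p under 0.05, and voom on recovered reads called 0, or 1 with median scaling; without DKO replicate 1 limma called 1. As a group, mature NK markers had a positive interaction in 24 of 28 members (median 0.32, adjusted p = 0.000154; adjusted p = 0.248 with an estimated correlation). Cell cycle genes had a negative one in 44 of 45 (median -0.69, adjusted p = 3.46e-13; adjusted p = 0.506 with an estimated correlation). Over all genes 0 members of either list passed, and adjusted over the list alone Itgam and Cdk1 did. Basophil and mast cell markers moved with them at a median of 1.67 (adjusted p = 0.000231; adjusted p = 0.627 with an estimated correlation).

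Of the 22 genes called in Id2KO against Ctrl, 22 had an interaction of the opposite sign, 19 of these with an unadjusted p under 0.05 and 0 past the adjusted threshold. Genes chosen for a large difference between Id2KO and Ctrl tend to show an opposite interaction by chance, since both contrasts use those libraries. In libraries simulated without interaction the opposite sign was seen in 83.5% of called genes and an unadjusted p under 0.05 in 31.7%, against 100% and 86.4% observed. Those simulations called 64 genes on average, more than the 22 observed, so their percentages are not matched to these genes. In DKO against Tcf1KO, which shares no library with the selecting contrast, 19 of the 22 kept their sign. Adjusted over these genes alone 11 passed with that sign, and over all genes 2 did (Id2 and Klrg1). Both contrasts use 1 spread per gene from the same fit. Genes selected by a small p tend to have a small spread, so these passes are not independent of the selection. The targeted gene Id2 is counted in the 19, the 11 and the 2. Gm16288, named after its values were seen, passed over these genes alone with the opposite sign. The median change of the 22 genes in the direction seen in Id2KO was 2.11 in Id2KO against Ctrl, a value raised by the selection, and 0.48 in DKO against Tcf1KO. Id2 RNA itself changed by -3.0 and -1.41 in these comparisons, so a smaller loss of Id2 may enter the smaller median. A change due to Cre, held only in Id2KO against Ctrl, may enter it as well.

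**Figure D3:**
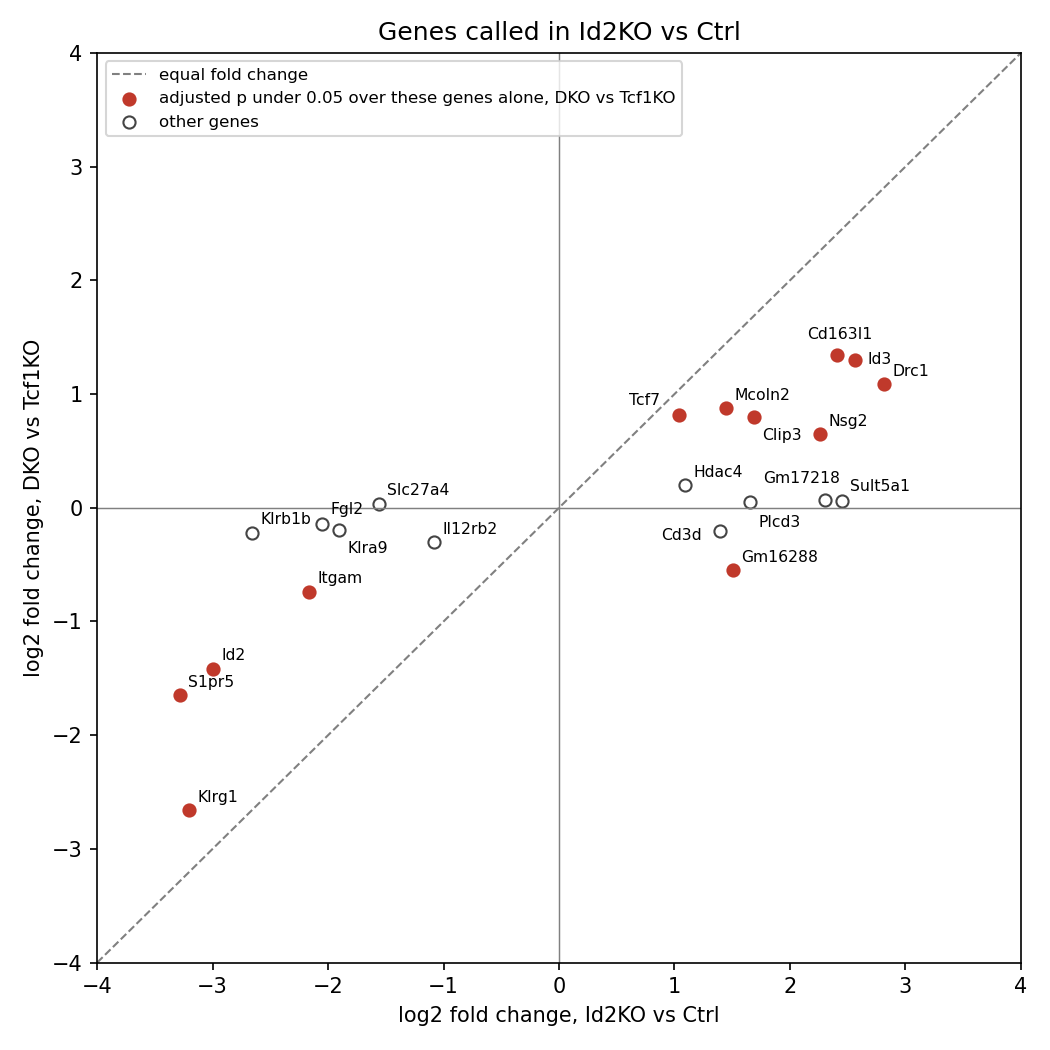
Log2 fold change of the 22 genes called in Id2KO against Ctrl (horizontal axis) and in DKO against Tcf1KO (vertical axis); the dashed line marks equal values, and filled points had an adjusted p under 0.05 over these genes alone in the second comparison. Klrg1 lay near the line at -3.2 and -2.66, while Klrb1b lay at -2.66 and -0.22.

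Across all tested genes, which are not independent replicates, the Id2 effects with Tcf7 not targeted and targeted (Id2KO against Ctrl, DKO against Tcf1KO) had a Pearson correlation of 0.24, a Spearman correlation of 0.19 and a covariance of 0.0575. The Tcf7 effects with Id2 not targeted and targeted (Tcf1KO against Ctrl, DKO against Id2KO) had values of 0.18, 0.14 and 0.0389. Neither pair shares a library. No p-value was planned for these 2 correlations. Exact 1-sided permutation tests of the covariance, added after seeing the data, gave p = 0.020 and p = 0.030 over 400 labelings each. Adjusted over both these were 0.030 and 0.030, and the smallest value the tests can give is 0.0050. They relabel both contrasts of a pair, so a strong effect in only 1 of them can lower p. Myeloid and erythroid markers were lower in both Id2 contrasts, so they enter the first covariance. Erythroid markers (medians 0.64 and 1.28), T cell receptor genes (0.72 and 0.35) and NKT markers (0.84 and 0.58) were higher in both Tcf7 contrasts, so they enter the second. With the DKO and Id2KO labels held, 1 of 20 labelings of Tcf1KO and Ctrl gave a covariance as large (exact permutation p = 0.050), and 0.050 is the smallest such value. The Id2 effects were not tested with labels held.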

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

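The tests in this part were chosen after the results were seen, apart from the interaction tests of the gene lists with their estimated correlation and fry forms, which were planned. Each list given first differed between the Id2 effect in DKO against Tcf1KO and that in Id2KO against Ctrl, by camera with the preset correlation. Id2KO against Ctrl also holds the presence of Cre, and DKO against Tcf1KO does not. The median interaction (log2) was 0.32 for mature NK markers, 0.19 for cytotoxic effectors, 0.73 for cytokines and chemokines, 0.17 for NK activating and inhibitory receptors, 0.23 for NK transcription factors and 0.26 for trafficking receptors and integrins. It was 0.56 for ILC1 and tissue-resident features, -0.69 for cell cycle genes, 0.63 for immediate early genes, -0.25 for interferon-stimulated genes, -0.23 for oxidative phosphorylation genes and 1.67 for basophil and mast cell markers. With an estimated correlation 0 of these lists passed (adjusted p = 0.248 for mature NK markers), and fry called 0. The preset test called 12 lists, against 7 without Ctrl replicate 1, Id2KO replicate 2 or Tcf1KO replicate 2 and 8 without Id2KO replicate 1. Without the 3 libraries that stand apart, the NK receptor, trafficking and interferon-stimulated lists had adjusted p = 0.0658, 0.0544 and 0.0517 in that test. With the replicate number as a block the NK receptor list had adjusted p = 0.0589.

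Other splits of the same libraries were counted for each comparison. For the interaction, 9 of 100 splits called as many lists as the real one (12; highest other 17), so chance is not excluded. Since the real split called 0 genes with limma (735 at an unadjusted p under 0.05, 0 by voom), all 100 splits reached that number and chance is not excluded there either. The split with the highest count called 26 genes and the next highest 2. The interaction splits mix libraries of all groups, so real differences between the groups can enter their counts. The highest count is 1 split, and what it follows was not tested. Groups of 3 make 10 splits, too few for a share under 0.05. The real split called 22 genes in Id2KO against Ctrl (highest other 1), 18 in DKO against Ctrl (2), 15 in DKO against Id2KO (0) and 7 in DKO against Tcf1KO (1). In these comparisons 1 split, the real one, gave as many genes. In Tcf1KO against Ctrl limma called 0 (594 at an unadjusted p under 0.05, 4 by voom), the highest other split 2, and all 10 gave as many. For the lists, the real and highest other counts were 14 and 14 in Id2KO against Ctrl, 5 and 10 in Tcf1KO against Ctrl, and 14 and 15 in DKO against Ctrl. They were 14 and 17 in DKO against Id2KO and 13 and 12 in DKO against Tcf1KO. In that order 2, 5, 2, 2 and 1 splits gave as many lists, the real one included.

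Mature NK markers were lower in Id2KO than in Ctrl while markers of basophil, myeloid and erythroid cells were lower too. Fewer cells of other lineages would raise members specific to NK cells and could lower only those that such cells also express, such as Itgam. With the other-lineage score as a term and an estimated correlation the list stayed lower (adjusted p = 0.00896, median -0.61 against -0.47 without the term), which argues against this as the whole cause. Cre alone would lower the list in Tcf1KO as well, yet its mean fold change there was 0.019 (library levels 0.010, -0.0053 and 0.051, against -0.89, -0.78 and -0.93 in Id2KO). This argues against Cre as the whole cause unless targeting Tcf7 offset it. The median there was -0.15, with 18 of 28 members lower, so a smaller part of Cre is not excluded. A change of NK cell maturation with Id2 targeted remains a hypothesis.

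Tcf7 RNA was not lower in the libraries labelled Tcf1KO, as controls or unrecombined cells would give. Controls without Cre would have Ncr1 at the level of Ctrl, yet it stood at 64.8 ± 5.14 FPKM against 192 ± 20.8 (log2 fold change -1.55, adjusted p = 0.143 over all genes), and each library of the 3 groups with Cre lay below each of Ctrl, which argues against such controls. The differences of these libraries from Ctrl covaried with those of DKO from Id2KO (exact 1-sided permutation p = 0.030), but with the DKO and Id2KO labels held p was 0.050, the smallest value 3 libraries against 3 can give. Erythroid and T cell markers, higher in both comparisons, enter this covariance as well, so unrecombined cells and other wrong labels stay open. Exons left after a deletion may still be counted in the gene total, and its change (log2 fold change -0.22) decides nothing without values per exon, so this stays open too.

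CD3 and T cell receptor RNA was higher in Tcf1KO than in Ctrl, and T cells in the sorted gate are a candidate explanation that stays open. The mean log2 level of Cd4, Cd8a, Cd8b1, Cd5, Cd6, Cd28, Themis and Bcl11b was higher by 0.78 (SE 0.23; 7 of 8 genes higher), by 0.89 in DKO and by 0.029 in Id2KO. But 7 of the 8 belong to the list in which the rise was seen, so this decides nothing. Trbc1 was not higher in Tcf1KO (246, 316 and 268 FPKM against 427, 447 and 318 in Ctrl). Trbc2, the other T cell receptor beta constant gene, was among the 10 members that rose adjusted over the list alone. The sort, as read from the labels, names no CD3 exclusion, and a change of these genes within NK cells was not tested.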

How the results depend on the processing

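The alternatives with voom, the Xist level, the other-lineage score and without the 3 libraries that stand apart (Id2KO replicate 3, DKO replicate 3 and Ctrl replicate 2) were chosen after seeing the data, as were the leave-one-out and block forms of the list tests. The counts of called genes were 22 for Id2KO against Ctrl, 0 for Tcf1KO against Ctrl, 18 for DKO against Ctrl, 15 for DKO against Id2KO, 7 for DKO against Tcf1KO, 0 for the interaction, 0 for opposite interactions and 5 for the overlap of Id2KO and DKO calls. Where not stated otherwise, the cause of a change was not tested.

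A fit of only the 2 compared groups, with fewer samples behind the spread, gave 2 for Id2KO against Ctrl, 1 for Tcf1KO against Ctrl, 1 for DKO against Ctrl, 0 for DKO against Id2KO and 1 for DKO against Tcf1KO. A threshold of 0.01 gave 10 for Id2KO against Ctrl, 1 for DKO against Ctrl, 3 for DKO against Id2KO, 0 for DKO against Tcf1KO and 1 for the overlap. A pseudocount of 0.1 gave 4 for DKO against Tcf1KO and 2 for the overlap. No filter gave 1 for Tcf1KO against Ctrl, 4 for DKO against Ctrl, 4 for DKO against Tcf1KO and 1 for the overlap, and a filter at FPKM 5 gave 8 for DKO against Id2KO and 4 for DKO against Tcf1KO. Array weights gave 7 for Tcf1KO against Ctrl and 3 for the overlap, and no variance trend gave 1 for the interaction and 1 for the opposite interactions; the cause was not tested. voom on recovered reads gave 4 for Tcf1KO against Ctrl, 2 for DKO against Tcf1KO and 2 for the overlap, and with median scaling 42 for Id2KO against Ctrl, 4 for Tcf1KO against Ctrl, 28 for DKO against Ctrl, 2 for DKO against Tcf1KO, 1 for the interaction, 1 for the opposite interactions and 10 for the overlap; the cause was not tested. The Xist level as a term gave 10 for DKO against Ctrl and 3 for the overlap. The other-lineage score as a term gave 11 for Id2KO against Ctrl, 7 for DKO against Ctrl, 8 for DKO against Id2KO and 1 for the overlap. Without the 3 libraries that stand apart the counts, from fewer samples, were 8 for Id2KO against Ctrl, 4 for Tcf1KO against Ctrl, 0 for DKO against Ctrl, 2 for DKO against Tcf1KO and 0 for the overlap. DKO against Id2KO then called 11 genes, 2 of them shared with the 15; the cause was not tested. Where these counts are 0, limma gave 1099 genes at an unadjusted p under 0.05 for DKO against Id2KO, 1046 for DKO against Ctrl and 834 for DKO against Tcf1KO.

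The labels do not say what the replicate numbers mark. Of 18 pairs of libraries with the same number, 6 had a correlation of residuals over 0.1 (range -0.14 to 0.27), so the numbers were not taken to pair the samples. As a hint from the data, not the design, 8 of 12 libraries were closest to their own number, and Tcf1KO and DKO replicates 1, 2 and 3 correlated by 0.20, 0.084 and 0.27. With the number as a block, DKO against Tcf1KO called 15 genes (3 higher, 12 lower). Of the called single gene results named in all contrasts, 10 no longer passed with the block and 39 still did. Of the uncalled ones 3 newly passed. The cause was not tested.

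Leaving out 1 library at a time gave 13 to 27 genes for Id2KO against Ctrl (lowest without Id2KO replicate 1), 0 to 3 for Tcf1KO against Ctrl (highest without Id2KO replicate 3), 1 to 27 for DKO against Ctrl (lowest without Ctrl replicate 1, Ctrl replicate 2 or DKO replicate 3, highest without Id2KO replicate 3), and 2 to 31 for DKO against Id2KO (lowest without Id2KO replicate 2, highest without Id2KO replicate 3). It gave 0 to 7 for DKO against Tcf1KO (lowest without Tcf1KO replicate 1, Tcf1KO replicate 3 or DKO replicate 3), 0 to 1 for the interaction (highest without DKO replicate 1), and 1 to 6 for the overlap. The remaining sample pair of a group is assumed to vary like the other groups.

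For the list tests an estimated correlation, which widens the test where members move together, gave 1 for Id2KO against Ctrl, 0 for Tcf1KO against Ctrl, 4 for DKO against Ctrl, 1 for DKO against Id2KO, 0 for DKO against Tcf1KO and 0 for the interaction in place of 14 for Id2KO against Ctrl, 5 for Tcf1KO against Ctrl, 14 for DKO against Ctrl, 14 for DKO against Id2KO, 13 for DKO against Tcf1KO and 12 for the interaction. fry gave 5 for Id2KO against Ctrl, 2 for Tcf1KO against Ctrl, 5 for DKO against Ctrl, 4 for DKO against Id2KO, 1 for DKO against Tcf1KO and 0 for the interaction. Without the 3 libraries that stand apart the lists were 10 for Tcf1KO against Ctrl and 8 for DKO against Tcf1KO, and with the other-lineage score 8 for Tcf1KO against Ctrl and 8 for DKO against Id2KO. Leaving out 1 library gave 4 to 10 lists for Tcf1KO against Ctrl, 6 to 14 for DKO against Id2KO and 7 to 14 for the interaction; the cause was not tested.

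The correlation of the Tcf7 effects with Id2 not targeted and targeted was 0.247 with a filter at FPKM 5 and 0.235 without the 3 libraries that stand apart. Of the alternatives to all these results, 314 stayed within 1.5 times the count or within the error of the correlation, 99 moved beyond it, and none changed the sign of a correlation. Counts of 0 that stayed at 0 are among the 314. For the 97 single gene results named, 2194 values under the alternatives kept their side of the threshold, 478 no longer passed it and 68 newly passed it. These pool called with uncalled results, and only called ones can stop passing. The direction was checked only for values that passed in the main fit or in the alternative, and it did not change there. Without the 3 libraries that stand apart, 39 called results no longer passed and 10 still did. With the other-lineage score as a term 27 no longer passed and 22 still did, and with median scaling 2 and 47. Library sizes of 13977524 to 20209587 reads limit the precision of genes near the filter.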

Other observations

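The observations in this part were chosen after the values were seen, and no explanation of them was tested. Cox6a2, a cytochrome c oxidase subunit, stood at 37.2, 35.2 and 24.4 FPKM in Id2KO and 28.5, 39.3 and 22.6 in DKO, against 12.5, 4.02 and 7.55 in Ctrl and 5.73, 5.15 and 13.8 in Tcf1KO. Ahr, the aryl hydrocarbon receptor, stood at 4.59, 4.79 and 5.03 FPKM in Id2KO and at 1.8, 0.939 and 2.28 in Ctrl (limma, adjusted p = 0.117). Itgb3, an integrin chain of platelets and some lymphocytes, stood at 6.42, 6.85 and 5.89 FPKM in Id2KO and at 1.68, 1.5 and 0.987 in DKO. Bst2, a tetherin gene induced by interferon, was at 4.11, 6.55 and 1.56 FPKM in DKO and at 17.9, 39.5 and 12.3 in Ctrl.

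Sex-linked RNA differed between libraries of each group. Xist, the RNA of the inactive X chromosome, was at 0.0664 FPKM in Ctrl replicate 1, 0.0598 in Id2KO replicate 2, 0.0845 in Tcf1KO replicate 1 and 0.129 in DKO replicate 1. In these libraries the Y-linked Ddx3y stood at 13.9, 15.2, 14.2 and 16.7 FPKM. DKO replicate 2 had both, with Xist at 124 and Ddx3y at 10.4 FPKM. In the other libraries Xist lay between 172 (Ctrl replicate 3) and 318 FPKM (DKO replicate 3), and Ddx3y was listed at 0 in each of them. With the Xist level as a term, DKO against Ctrl called 10 genes in place of 18.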
